A study of Mus musculus with 2 samples.

How the data were processed

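Total RNA of B16 mouse melanoma cells was extracted with Trizol, depleted of ribosomal RNA and made into stranded libraries, per the labels' protocols. There were 2 libraries, 1 of control-treated and 1 of LY500307-treated cells. Dose and time of treatment are not given in the sources used here. CASAVA 1.8 and Bowtie2 were used with the mouse build mm9, per the submitters' processing notes. The counting tool, the annotation release, any filter and the scaling are not given in the sources used here.

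The deposited values are a signal per gene. The values themselves show them to be read counts multiplied by 1 factor per library and not divided by gene length. In each library successive values differ by a constant step, 0.944 for a read in the control and 1.06 in the LY500307 library. Dividing by the step gave whole reads, within 1% of a read, for 99.9% of control values and 100% of LY500307 values. The recovered totals were 16704950 and 14698853 reads, and the deposited totals 15776861 and 15563532. A gene with no read is listed at a value near 0 and was set to 0. A single read was worth 0.0603 and 0.0676 CPM.

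The deposited values were divided by the mean of both totals to give counts on the CPM scale. The design had assumed length-normalised values or raw counts, and the same rules were applied to these CPM values instead. A comparison with fold changes of the authors was planned, but no such column was used here, and it was not made. Symbols were taken for 18183 of 18224 identifiers from a table of gene names, 41 had none, and 10 entries that share a symbol were summed, which left 18219 genes. Biotypes, transcript lengths, GC content and near-identical copies came from GENCODE M21, which uses another build, so no positions are given.

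The main measure was log2((LY500307 + 1)/(control + 1)) for the 12243 genes with a mean of at least 1 CPM. With 1 library per group there is no test between treatments, and genes were counted by a rule of 2-fold. Counting intervals are exact Clopper-Pearson intervals at 95% of the plain ratio of recovered reads. For 32 gene lists the median over measured members, with at least 5 of them, was given as a percentile among 10000 random lists drawn in 20 bins of mean expression. Reads from PCR without molecular identifiers are not independent molecules. An exact binomial test of the recovered reads with Benjamini-Hochberg adjustment, which compares the libraries and not the treatments, was added after the data were seen.

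Genes were named by a fixed rule. It takes the 12 largest log2 folds per direction among genes that are not predicted models, small structured RNAs or receptor segments, up to 4 members with the largest absolute fold of each list outside its range and up to 2 of each other list. Receptor, inflammasome and cytokine genes of interest, pigment genes, Actb and Gapdh are always named. Groups, the 2-fold rule, the lists, the rule for names and most alternatives were fixed before the data were examined.

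Alternatives were other pseudocounts, expression minimums, thresholds and scalings, other handling of shared symbols, other matching of random lists, and leaving out small RNAs, histones and predicted models. Those added after the data were seen were reads over each library's own total, centring within bins of GC content and length, sums over or removal of near-identical copies, the mean of a list and the binomial test. A near-identical copy was an M21 gene whose longest transcript matched at 95% identity or more over at least 100 bases and 50% of the shorter transcript, by blastn 2.17.0.

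The calculations were tested on simulated data for 18219 genes with counting error only, for LY500307 against control, with 200 genes changed. All 50 genes changed 4-fold and 45 of 50 changed 2.5-fold passed the 2-fold rule, as did 40 of 49 lowered to 0.4 of the control level and 0 of 50 changed 1.5-fold. Of 12005 unchanged genes 0 passed, and intervals held the true value for 95.6% of them. The binomial test called 39 of the 50 genes changed 1.5-fold and 9 unchanged genes. A list of 20 genes shifted by 0.3 on the log2 scale reached the 100th percentile and an unshifted list the 36.0th. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.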

Results

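RNA was sequenced from 2 groups of B16 cells, a mouse melanoma line that makes pigment, 1 given a control treatment and 1 treated with LY500307. Whether a library came from 1 culture or from several pooled is not given in the sources used here. LY500307, also named erteberel, is a synthetic agonist selective for estrogen receptor beta. Each group was a single library, so no difference below has a replicate check, and every value describes these 2 libraries and not the treatments in general. The control library held 16704950 reads recovered from the deposited values and the LY500307 library 14698853, over 18224 listed genes. No read was recovered for 679 of these genes in the control library and for 788 in the LY500307 library. Mitochondrially encoded genes took 2.60% of the control values and 2.87% of the LY500307 values, and the 10 most abundant genes took 6.68% and 6.91%. Intervals given below are exact 95% intervals of the ratio of reads and cover counting error only.

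The comparison of the treated with the control library asked which transcripts differ in melanoma cells given the agonist. Most genes lay close together in both libraries. Folds were taken on the scale log2(CPM + 1), which understates the difference of low genes. The CPM values are read counts scaled by 1 factor per library. Of 12243 genes with a mean of at least 1 CPM, 31 were at least 2-fold higher and 15 at least 2-fold lower in the LY500307 library. These 46 genes were 0.376% of those measured, and 96.4% of genes lay within 1.5-fold. The median log2 fold was -0.01, with a 5th percentile of -0.36 and a 95th percentile of 0.43. Across genes, which are not independent replicates, Pearson's r of the log2 values was 0.993. For genes with a mean between 1 and 5 CPM the 5th and 95th percentiles were -0.60 and 0.65, and at 100 and above they were -0.24 and 0.20. Of the 46 genes, 35 were protein coding and 6 were pseudogenes, and 18 had a near-identical copy elsewhere in the annotation, so that their share of the reads is uncertain. These 18 were 8 of the 31 higher and 10 of the 15 lower genes. How strand was used in counting is not given in the sources used here, so genes that overlap an antisense partner are uncertain as well.

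**Figure D1:**
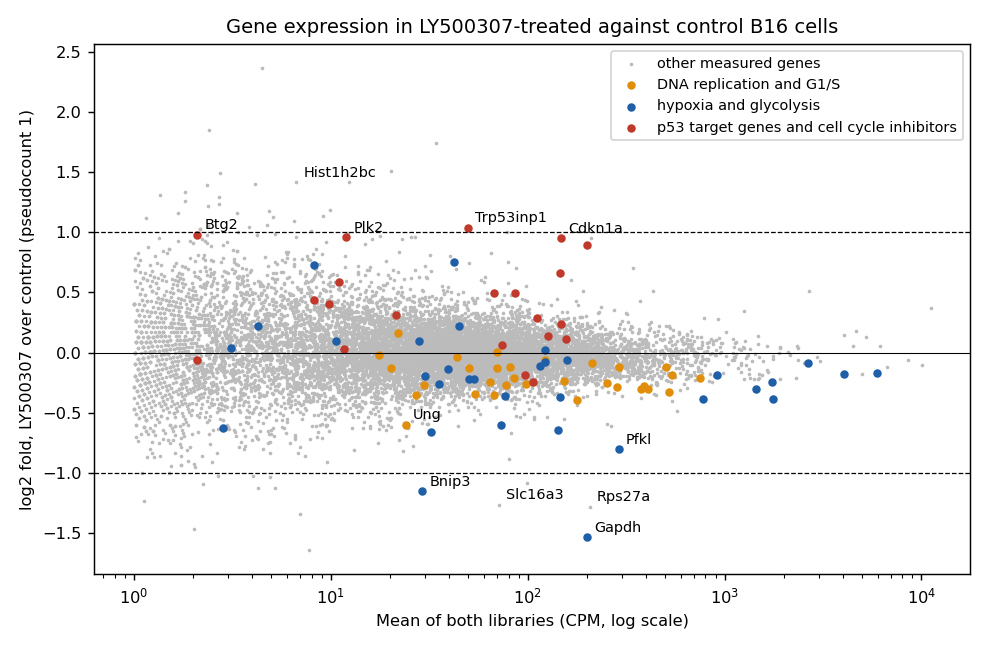
Log2 fold of the LY500307 over the control library (vertical axis, pseudocount 1) against the mean of both libraries in CPM (horizontal axis, log scale), 1 point per gene for the 12243 measured genes. Dashed lines mark 2-fold, and the coloured points are the members of 3 gene lists. Most p53 targets and cell cycle inhibitors lie above 0, while most replication, hypoxia and glycolysis genes lie below it.

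The named genes with the largest positive log2 folds had low or moderate expression. Tmem254c had a log2 fold of 1.85, Smtnl1 of 1.49, the histone gene Hist1h2bc of 1.42, Dglucy of 1.41, Adh7, an alcohol dehydrogenase, of 1.40, and Tle6 of 1.40. Traf3ip3 followed at 1.31, Cib2 at 1.29, the carboxypeptidase gene Cpz at 1.23, Pdcd4, an inhibitor of translation, at 1.18, the diacylglycerol kinase gene Dgki at 1.17 and Ddit4l at 1.16. Dglucy went from 6.33 to 18.5 CPM, a 2.93-fold ratio of reads (2.33 to 3.70). Pdcd4 went from 5.67 to 14.1 CPM. The pseudocount of 1 lowers the folds of genes on few reads and changes their order. Without it, Tmem254c, on 8 and 64 reads, had a log2 ratio of 3.17 (interval 2.10 to 4.44), Traf3ip3, on 6 and 35, of 2.71 (1.44 to 4.25), Smtnl1, on 16 and 67, of 2.23 (1.43 to 3.12) and Tle6, on 14 and 57, of 2.19 (1.33 to 3.15).

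Several genes at the other end were abundant. Gapdh (ENSMUSG00000057666), a glycolytic enzyme often used as a reference gene, was at 299.6 CPM in the control and 102.8 in the LY500307 library, a log2 fold of -1.53 with an interval of -1.63 to -1.46. The mean of Gapdh over both libraries was 201.2 CPM. The glycolytic genes Eno1, Pkm, Aldoa, Tpi1, Pgk1 and Ldha had means of 1448 to 5950 CPM, and Pfkl of 290.3. Whether reads of Gapdh were lost in both libraries was not tested. Rps27a, which encodes a ubiquitin and ribosomal protein fusion, had a log2 fold of -1.28. Slc16a3, a lactate exporter, was at 101.0 and 41.5 CPM (-1.26, interval -1.42 to -1.15), and Bnip3, a mitochondrial protein of the BCL2 group induced by low oxygen, at 40.6 and 17.7 (-1.15, interval -1.41 to -0.99). Sumo2, a ubiquitin-like modifier, had a log2 fold of -1.08, Kbtbd11 of -1.13, Loxl2, a lysyl oxidase, of -1.03, Abhd18 of -1.03, Dqx1 of -1.02 and the connexin gene Gjb1 of -0.998, on 30 and 6 reads (-2.16 without the pseudocount). The pseudogenes Rpl30-ps10 and Rpl30-ps1 were at -1.34 and -1.09. Gapdh, Rps27a, Sumo2, Bnip3, Loxl2, Dqx1, Hist1h2bc and both Rpl30 pseudogenes have near-identical copies among the listed genes, and the counting could have divided reads among these. Summed with their listed copies, Sumo2 came to -0.34 and Loxl2 to -0.96. The others stayed past 2-fold, Rps27a (-1.005) and the Rpl30 pseudogenes (-1.004) only just. The sum of the Rpl30 pseudogenes leaves out Rpl30 itself, which went from 294.3 to 352.0 CPM. Reads moved between these pseudogenes and Rpl30 therefore stay open. Of the 46 genes past 2-fold, 18 had a near-identical copy and 17 a listed one, so a gene with only unlisted copies may be missing here.

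Gene lists fixed before the data were examined showed which groups of genes stood apart. Of 32 lists, 30 had at least 5 measured members, and each median was set against 10000 random lists of the same size matched on expression. The median lay outside the central 95% of its random lists for 16 lists, 12 on the higher and 4 on the lower side, where the rule alone gives 1.5. Several lists share genes, so these 16 are not independent. The random lists were drawn gene by gene and do not keep any tendency of list members to vary together. The 1.5 is therefore not a chance level for such lists. The percentiles describe these libraries and do not test the treatment.

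Targets of p53 and inhibitors of the cell cycle had the highest median of these lists. The median log2 fold of the 21 measured members was 0.41, above each of the matched random lists, whose central 95% ran from -0.10 to 0.08. Counting intervals lay above 0 for 16 members and below 0 for 2, where random lists gave 3.83 and 4.52. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was at 100.6 CPM in the control and 195.1 in the LY500307 library, a 1.94-fold ratio of reads (1.82 to 2.06). Trp53inp1, a p53-induced nuclear protein, went from 32.2 to 67.2 CPM (log2 fold 1.04), and the antiproliferative gene Btg2 and the kinase gene Plk2 had log2 folds of 0.98 and 0.96. The cyclin-dependent kinase inhibitor genes Cdkn1b and Cdkn2c, named after their values were seen, were the 2 members with intervals below 0, at -0.18 and -0.25. Genes of the BCL2 family, caspases and death receptors had a median of 0.12 (99.84th percentile), with intervals above 0 for 11 of 28 members and below 0 for 5. In that list Bmf and Bbc3, which promote cell death, had log2 folds of 0.64 and 0.41, the death receptor gene Tnfrsf10b 0.59, and Bcl2l1, a gene of cell survival, 0.33. Bbc3 and Tnfrsf10b, with Bax, Fas and Pmaip1, belong to the p53 list as well, so the 2 lists are not separate evidence.

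Genes of DNA replication and of mitosis were lower in the LY500307 library as groups, by small amounts. The 31 replication genes had a median log2 fold of -0.24 and the 34 mitosis genes of -0.13, both below each of their random lists. Intervals lay below 0 for 24 replication genes and 24 mitosis genes, and above 0 for none of either list. The uracil-DNA glycosylase gene Ung had a log2 fold of -0.60, the replicative helicase subunit gene Mcm4 of -0.39, the polymerase alpha gene Pola1 of -0.36 and Gins1 of -0.35. Among the mitosis genes the spindle gene Aspm was at -0.41, the topoisomerase gene Top2a at -0.29, the phosphatase gene Cdc25b at -0.26 and the kinase gene Plk1 at -0.25.

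Genes of hypoxia and glycolysis were lower as well. Their median over 33 measured members was -0.20, below each of the random lists, with intervals below 0 for 22 members and above 0 for 3. Over the 23 members without a near-identical copy the median was -0.11 (1.27th percentile). Beside Gapdh and Bnip3, the phosphofructokinase gene Pfkl was at 369.2 and 211.4 CPM (log2 fold -0.80). Ddit4, an inhibitor of mTORC1 that responds to several stresses, went the other way, from 31.2 to 53.4 CPM (0.76).

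**Figure D2:**
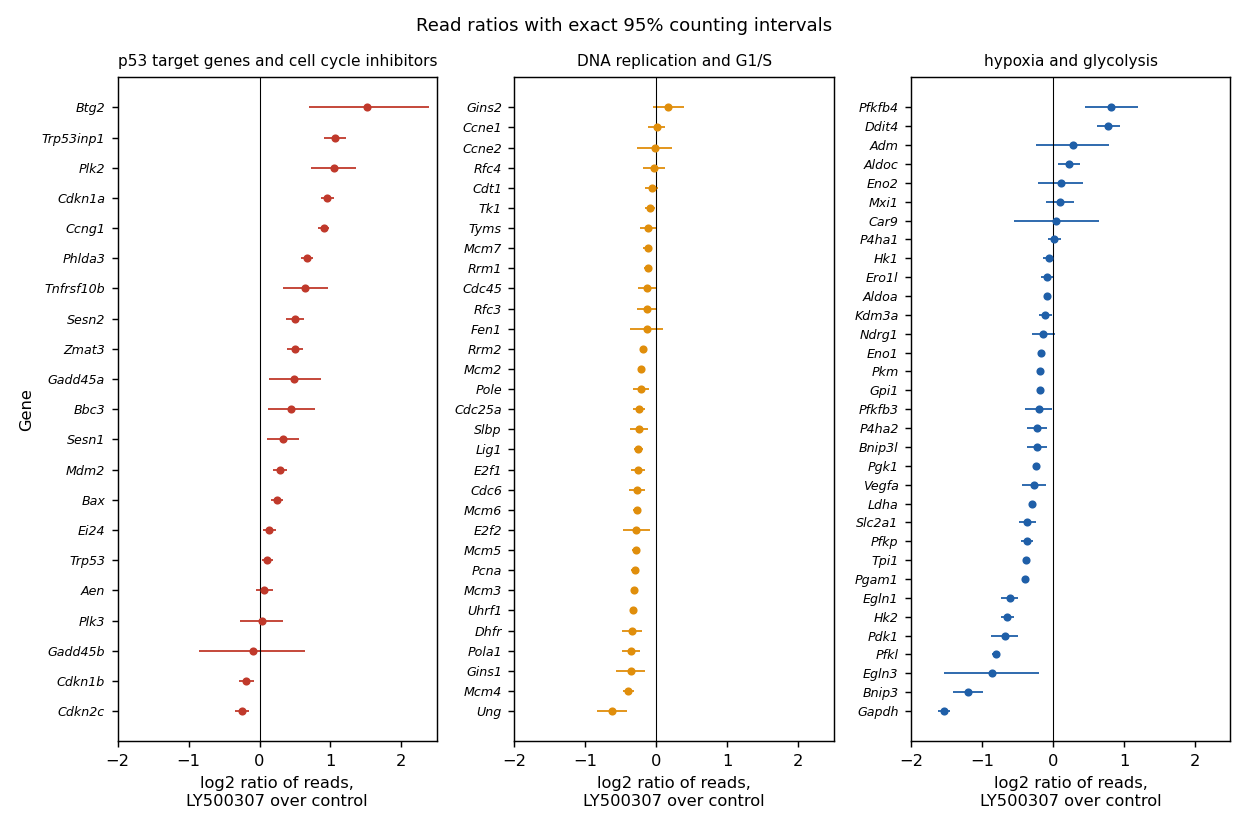
Log2 ratio of reads, LY500307 over control (horizontal axis), for each measured member of the p53 target, DNA replication and hypoxia lists, as points with exact 95% counting intervals. Intervals lie above 0 for 16 of 21 p53 targets and cell cycle inhibitors. They lie below 0 for 24 of 31 replication genes and 22 of 33 hypoxia and glycolysis genes.

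Genes of the oxidative stress response and targets of the transcription factor NRF2 were higher in the LY500307 library. Their median was 0.17, above each of the random lists, and intervals lay above 0 for 20 of 26 members and below 0 for 1. Slc7a11, the cystine importer subunit, had a log2 fold of 0.69, the quinone reductase gene Nqo1 of 0.54 and the glutathione transferase gene Gstm1 of 0.53. Fth1, the ferritin heavy chain, was among the most abundant genes and went from 2214 to 3160 CPM (0.51, interval 0.49 to 0.53). Cytosolic ribosomal protein genes had a small median of 0.06, above each of their random lists, with intervals above 0 for 39 of 66 genes and below 0 for 4. Rpl30 was at 0.26, Rpl34 at 0.20 and Rps12 at 0.19, while Rps27a was at -1.28. Only 5 members had no near-identical copy, and their median was 0.11 (98.35th percentile).

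Of the lists of immune and inflammatory genes, 3 lay above their range, with modest medians, and the inflammasome, cytokine and toll-like receptor lists lay inside theirs. Interferon-stimulated genes had a median of 0.18 (99.11th percentile; intervals above 0 for 8 of 20 and below 0 for 2), genes of class I antigen presentation and checkpoints 0.14 (98.7th; 6 of 14 and 1) and NF-kappaB feedback and target genes 0.13 (98.41st; 6 of 17 and 2). The antiviral genes Ifitm3, Ifih1 and Rsad2 had log2 folds of 0.77, 0.62 and 0.61, while the guanylate-binding protein gene Gbp3 was at -0.74. The peptide transporter gene Tap1 was at 0.86, on 13 and 33 reads, and the class I genes H2-Q4 and H2-D1 at 0.41 and 0.30, with the peptidase gene Erap1 at 0.35. Tnfaip3 and Birc3, both induced by NF-kappaB, were at 0.69 on few reads, Tnfaip2 at 0.36 and Tnip1 at 0.28. The class I list was at the 97.3rd percentile with random lists matched on transcript length as well, and the NF-kappaB list at the 97.11th with a mean of at least 5 CPM, both just inside the central 95%.

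Signalling, adhesion and lysosome lists also lay on the higher side. Immediate early genes were at 0.19 (99.78th percentile), with intervals above 0 for 9 of 23 and below 0 for 4. Btg2, which is in the p53 list as well, was at 0.98, Nr4a2 at 0.61, Fos at 0.60 and Nr4a3 at -0.61. Genes of the TGF-beta response and epithelial-mesenchymal transition were at 0.13 (99.69th; 7 of 16 and 1), with the integrin genes Itgb3 and Itga5 at 0.50 and 0.37, Snai2 at 0.39 with an interval that includes 0, and Smad7 at 0.31. Matrix protease and adhesion genes were at 0.09 (99.5th; 11 of 22 and 4), with the protease inhibitor gene Timp3 at 0.95, the adhesion genes Mcam at 0.45 and L1cam at 0.43, and Mmp15 at -0.39. Genes of MAPK output were at 0.11 (97.9th; 4 of 18 and 3, where random lists gave 3.12 and 3.46), with Etv5 at 0.54, Epha4 at -0.50 and Egr1 at 0.39, the last 2 with intervals that include 0. That list was at 0.040 (83.5th percentile) with a mean of at least 5 CPM, and its mean was 0.07 (83.46th). Lysosome and autophagy genes were at 0.05 (98.63rd; 10 of 34 and 4), with the autophagy receptor gene Sqstm1 at 0.34, Atg7 and the cathepsin gene Ctsd both at 0.28, and Rragd at -0.27. Against random lists not matched on expression the lysosome list was at the 91.5th percentile and the adhesion list at the 97.29th.

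The list named nuclear long non-coding RNAs, which also holds host transcripts of small RNAs, had the lowest median, -0.27 over 11 members (0.06th percentile). Of these, 6 were lower and 5 higher, and intervals lay below 0 for 4 members and above 0 for 2. The mean of the list was -0.15 (2.54th percentile), inside the central 95%. Mir17hg, the host transcript of a microRNA cluster, had a log2 fold of -0.83, the snoRNA host transcripts Snhg1 and Gas5 of -0.60 and -0.39, and Dleu2 of -0.35. Long non-coding RNAs as a class were not lower to that extent. By annotated biotype, 177 lincRNA genes had a median of 0.001 (27.95th percentile of 1000 random lists) and 118 processed transcripts of -0.05 (2.1st).

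**Figure D3:**
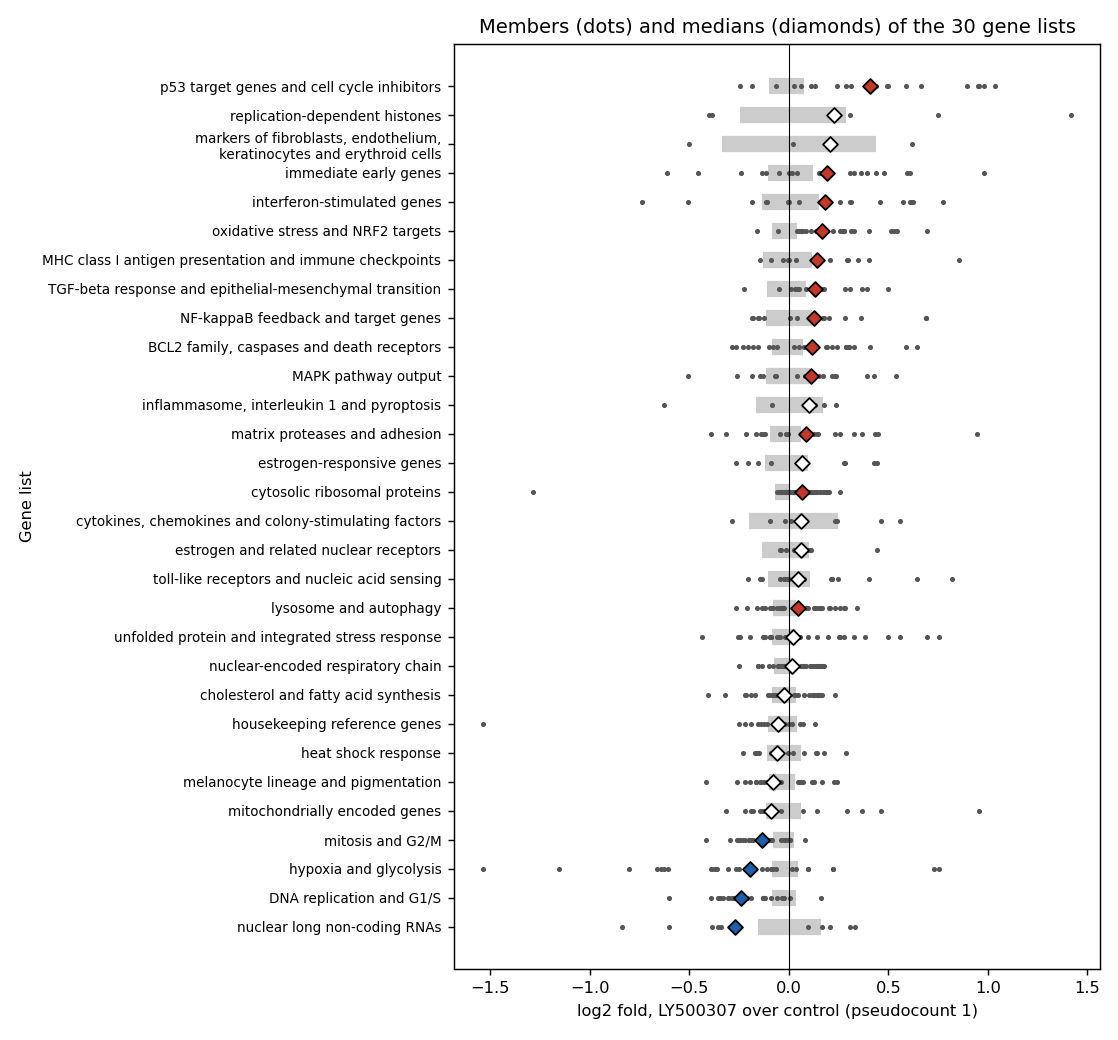
Log2 fold of LY500307 over control (horizontal axis, pseudocount 1) for the measured members of 30 gene lists (vertical axis), as dots, with the list median as a diamond and the central 95% of 10000 expression-matched random medians as a grey bar. Red and blue diamonds are the 12 medians above and the 4 below that range, and white diamonds lie inside it.

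The medians of the remaining lists lay inside the central 95% of their random lists, but the means of 5 of them lay outside. Melanocyte and pigment genes had a median of -0.08 (6.83rd percentile), and the main pigment genes were close in both libraries. Tyr was at -0.06, Tyrp1 at -0.10, Dct at 0.06, the lineage transcription factor gene Mitf at -0.11, Mlana at -0.04 and Pmel at -0.12, with Kit at -0.42 on few reads and Mlph at -0.26. Housekeeping genes had a median of -0.05 (27.1st) and Actb a log2 fold of 0.00, but the mean of that list, which holds Gapdh, was -0.14 (0.18th). Pgk1, a glycolytic enzyme of the same list, was at -0.25. Mitochondrially encoded genes had a median of -0.09 (7.27th) and a mean of the opposite sign, 0.06. In that list the ribosomal RNA gene mt-Rnr1 was at 0.95 and mt-Atp8 at 0.47. The libraries were depleted of ribosomal RNA, so the fold of mt-Rnr1 is uncertain. Nuclear genes of the respiratory chain were at 0.02 (95.8th; mean 0.02, 97.56th), with Uqcrfs1 at -0.25 and Cox7a2 at 0.18. Replication-dependent histones were at 0.23 (94.3rd; mean 0.30, 98.45th) over 8 members, with Hist3h2a at 0.75. Genes of the unfolded protein response were at 0.02 (93.6th; mean 0.07, 99.69th), of heat shock at -0.06 (22.7th), with Hspa4l at 0.29 and Hsf1 at -0.23, and of cholesterol and fatty acid synthesis at -0.02 (49.3rd), with Fdps at -0.41 and Insig1 at -0.32. Toll-like receptor and nucleic acid sensing genes were at 0.05 (83.2nd; mean 0.13, 98.19th), with Tlr3 at 0.82 and Myd88 at 0.64.

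The estrogen receptor gene Esr1 had few reads in both libraries. Esr2, which encodes estrogen receptor beta, was not analysed here. Esr1, the alpha receptor, had 1 read in the control and 6 in the LY500307 library, with a log2 ratio interval of -0.29 to 8.27. Estrogen and related receptors and their cofactors had a median of 0.06 (90.95th percentile) over 8 measured members, with Nrip1 at 0.44 and Ncoa1 at 0.11. Estrogen-responsive genes had a median of 0.07 (93.0th) over 11 members, with intervals above 0 for 4 and below 0 for 3, and the cyclin gene Ccnd1 was at 0.43.

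Several inflammasome genes were also near the detection limit. Il1b, which encodes interleukin 1 beta, had 0 reads in the control and 6 in the LY500307 library, at least 2.24-fold higher against a floor of 3 reads in the control library if the 6 reads are taken as exact. With the counting error of both libraries the exact interval of its ratio starts at 1.32-fold. Casp1 had 0 and 2 reads, Gsdmd 7 and 12, and Il18 16 and 14, and a difference was not detectable at this depth for these 3 genes. Il1a, Nlrp3, Cxcl1 and Csf3 were not analysed here. The inflammasome list had a median of 0.10 (88.7th) over 7 measured members, with Txnip, a thioredoxin-binding protein, at -0.63 and Gsdme at 0.24. The mean of that list was 0.0013 (48.35th), and with no expression minimum its median was 0.18 (99.76th). Cytokines, chemokines and colony-stimulating factors were at 0.06 (70.0th) over 9 members, with Lif at 0.56 and Tgfb3 at 0.46.

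Markers of other cell types were low in both libraries. Of 27 leukocyte markers only Cd68 reached the expression minimum, at 1.51 and 1.35 CPM. Markers of fibroblasts, endothelium, keratinocytes and erythroid cells had a median of 0.21 (82.4th) over 5 members, with Col1a1 at 0.62 and Col1a2 at -0.50. Of 20 structured small RNAs, 2 were measured, Rpph1 at -0.39 and Rn7sk at -0.31, each with an interval that includes 0.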

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

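Alternatives with recovered reads over each library's own total, GC and length centring, near-identical copies, the mean of a list or the binomial test were chosen after seeing the data, and the rest before. The number of genes at least 2-fold higher and lower moved with the handling of low values and with the threshold. It was 109 and 71 with a pseudocount of 0.1, 126 and 89 with 0.01, and 10 and 8 with a mean of at least 5 CPM. At a threshold of 1.5-fold it was 275 and 170, and at 4-fold 1 and 0. The binomial test of the reads, which has no minimum size, called 1472 and 1717. Of the 16 lists outside their random range, 10 stayed outside under all 15 alternatives, among them p53 targets (0.31 to 0.45), replication (-0.25 to -0.21), mitosis, NRF2 targets and hypoxia (-0.24 to -0.11, the last without near-identical copies). With a mean of at least 5, NF-kappaB genes were at 0.11 (97.11th percentile) and MAPK genes at 0.040 (83.5th). With unmatched random lists, matrix genes at 0.088 were at the 97.29th percentile and lysosome genes at 0.046 at the 91.5th. Class I genes were at 0.14 (97.3rd) with matching on length and at 0.12 (97.36th) after centring. Without near-identical copies, MAPK genes were at 0.062 (88.2nd) and lysosome genes at 0.038 (96.5th). By the mean, NF-kappaB genes were at 0.13 (97.48th), MAPK genes at 0.071 (83.5th) and nuclear long non-coding RNAs at -0.15 (2.54th). The cause was not tested for these lists. None of the 16 lists changed sign, but lists inside their range in the main analysis did, namely mitochondrially encoded genes (0.057 by the mean), the unfolded protein response (-0.0048 without near-identical copies) and cytokines (-0.0025 with a mean of at least 5), as did Actb (-0.0050 with trimmed-mean scaling). Further, 6 of 116 named genes moved by more than the distance from the middle of their counting interval to its end. Of the 14 other lists, 7 crossed the range under at least 1 setting, among them inflammasome genes with no expression minimum (0.18, 99.76th). Depth limits genes of a few reads such as Il1b and Esr1, for which 1 read is worth 0.0603 or 0.0676 CPM. No paired analysis was possible because each group has 1 library and the results come from no test.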

Other observations

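The tests in this part were all chosen after the values of genes and lists had been seen, and only those of GC content and length, of ribosome biogenesis and of genes with as many copies as Gapdh had their bounds set before the result each measures was seen. Further gene lists were written at that stage too, when single members of some had been seen. Proteasome subunit genes were higher in the LY500307 library as a group, with a median log2 fold of 0.09 over 31 genes, above each of 10000 matched random lists. Of these 31 genes 28 were higher and 18 had an interval above 0, against none below. Psmd8 went from 278.2 to 350.3 CPM (0.33), and Psmb4 and Psmb6 were at 0.24 and 0.23; genes of these further lists were picked for naming after their values were seen. Cytosolic aminoacyl-tRNA synthetase genes were at -0.02 (62.8th percentile) and Notch pathway genes at 0.07 (81.0th), although the receptor genes Notch1 and Notch3 were at 0.93 and 0.92, at 1.27 and 1.02 CPM in the control library. Glycolytic enzymes within the fixed hypoxia list had a median of -0.22 over 18 genes, below each random list, and the other 15 members of -0.14 (1.02nd).

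Inflammasome and pyroptosis genes under the expression minimum were added up, which was also chosen after their values were seen. Over 9 such genes, Aim2, Casp1, Casp4, Gsdmd, Il18, Il1b, Nlrc4, Nlrp1a and Nlrp1b, there were 29 reads in the control and 52 in the LY500307 library, a 2.01-fold ratio (1.25 to 3.28). Of the 9 genes 7 had more reads in the LY500307 library, Nlrc4 had 1 read in each and Il18 had fewer. The same sum was made for 22 lists, and 1 interval, this one, lay off 1, where chance alone gives up to 1.1, so the sum does not set this list apart. All 5976 genes with reads under the minimum gave a ratio of 0.998.

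Reads shared between near-identical copies are a candidate explanation for part of the 46 genes at least 2-fold apart. Of these, 18 had such a copy, against a mean of 9.89 in matched random lists, whose central 95% ended at 16, and 28 had none. The 18 were 8 higher and 10 lower genes, and the 28 were 23 higher and 5 lower. The question thus bears most on the lower side. Rpl17 was at -0.89 and its pseudogene Rpl17-ps10 at 0.998, and Rpl17 with its 8 listed copies summed to 0.12, while Sumo2 was at -1.08, its copy Gm10241 at 1.74 and Sumo2 with its 7 listed copies at -0.34. Of 14 distinct families with listed copies, 7 came under 2-fold when summed (9 of 17 when counted by gene), exactly the share set as the bound, with 2 of the 7 only just under, and a sum with an abundant copy also dilutes a minor member, so this count decides nothing. The Gapdh family stayed at -1.53 when summed over the 2 listed of its 3 copies, which argues against reads moved between listed copies as the cause for Gapdh. The 779 other genes with at least 3 copies had a median of -0.014 (21.1st percentile), 417 lower and 362 higher. This argues against a loss of ambiguous reads shared by most such genes. A median cannot show a loss at only some of them, so reads lost at Gapdh alone or at part of these genes stay open.

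The higher p53 target list and the lower replication list may reflect slower cycling under LY500307, a hypothesis from the same data. GC content and transcript length as the whole cause are argued against, since after centring on both the p53 list was at 0.37 and the replication list at -0.23, and 15 of 30 lists still lay outside their range. A further list of 24 measured p53 targets had a median of 0.046 (83.8th percentile) and a bootstrap interval of -0.04 to 0.13. Intervals lay above 0 for 7 and below 0 for 2 (4.07 above 0 in random lists, 93.2nd percentile). This argues against a shift like the 0.41 of the fixed list across these 24 targets and leaves a response of some of them open. The 2 lists share no gene and may respond to p53 by different amounts. The comparison therefore does not decide whether p53 was more active. Ribosome biogenesis genes were lower, with a median of -0.12 over 30 genes (0.05th percentile) and intervals below 0 for 17 and above 0 for none, as a lower output of growth genes needs by the bound set beforehand, while ribosomal protein genes (0.06), most with near-identical copies, and aminoacyl-tRNA synthetase genes (-0.02) were not below their random lists, so how general it was stays open. The density, age or handling of the cells behind each single library was not tested and stays open beside the treatment.

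The lower hypoxia and glycolysis list is a further pattern for which a weaker hypoxia-factor programme is a candidate explanation. After centring on GC content and length its median was -0.20, which argues against these as the cause. A further list of hypoxia-induced genes without glycolytic enzymes had a median of -0.22 over 23 measured members, below each random list, with intervals below 0 for 12 and above 0 for none, as that explanation needs. Fam162a, a hypoxia-induced mitochondrial gene, was at -0.37 and the adenylate kinase gene Ak4 at -0.58. A difference in oxygen or cell density between the 2 groups of cells would give the same pattern and was not tested.

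Further snoRNA host genes, 18 measured, had a median of -0.10 (3.34th percentile; bootstrap interval -0.19 to -0.01), inside the range of their random lists, with intervals above 0 for 3 and below 0 for 6.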
